A study of Homo sapiens with 14 samples.

How the data were processed

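Polyadenylated RNA of HEK293T cells was sequenced in 14 libraries prepared with the TruSeq RNA v2 kit, per the labels' protocols, a kit that does not mark the strand of the transcript. The values analysed were whole-number read counts per gene, deposited by the authors as one table of 63140 genes by 14 libraries. Per the submitters' processing notes the tools were STAR 2.7.11a, featureCounts of Subread 2.0.3 and edgeR 3.42.4 with the genome build GRCh38, and neither the annotation release nor the strand setting of the counting is given in the sources used here. The counts had not been normalised, filtered or pooled as far as the values show, since the totals differ from 22.24 to 36.26 M and 21677 genes have no count in any library. All 14 columns matched the labels of 1 sample each. Libraries were grouped by the treatment in the labels into control (n = 5), miR-34a-WT (n = 5) and miR-34a-RS (n = 4).

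The common biological coefficient of variation, the spread between libraries beyond counting error, was 0.062. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom from 2.73 to 14.24 over 26 pairs, so each library counted as 1 replicate. Intervals are at the 95% level.

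Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group, and glmQLFit and glmQLFTest with robust dispersion over all 14 libraries in one fit of 3 group means. Benjamini-Hochberg adjustment ran over the 18321 tested genes, with a threshold of 0.05. CPM values are scaled by TMM, and log2 CPM values for shifts used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 on voom values with the preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. The 20 lists were reported miR-34a targets, p53 target genes, G1/S and DNA replication, G2/M and mitosis, Notch signalling, Wnt signalling, the interferon and double-stranded RNA response, small RNA machinery, the integrated stress response, the unfolded protein response, cholesterol biosynthesis, the BCL2 family, glycolysis, epithelial-mesenchymal transition, receptor tyrosine kinases and RAS-MAPK, synaptic vesicle and exocytosis, lysosome and autophagy, mitochondrially encoded genes, fibroblast markers and blood cell markers.

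The same replicate numbers occur in all groups, but the labels do not say what a number marks. The deviations of each library from its group mean were therefore correlated over 10372 genes. Between miR-34a-RS and miR-34a-WT, same-numbered libraries correlated at 0.39 to 0.76 (mean 0.59, against -0.14 for other pairs), and each correlated best with its own number, so the numbers were taken as pairs for this comparison, and the fit with the replicate number as a block is given beside its results where it changes a call or moves a count by over 1.5 times. The fit used for the first values has no block, and counts of list members are given from that fit only.

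Sites were searched in the 3′ UTR of 1 transcript per gene, the longest 3′ UTR of at least 20 bases in GENCODE 29, which holds 99.71% of the counts by gene identifier, and 13608 tested genes had one. The guide was UGGCAGUGUCUUAGCUGGUUGU and the passenger CAAUCAGCAAGUAUACUGCCCU. Seed matches were 8mer, 7mer-m8, 7mer-A1 (ACTGCCA) and 6mer (ACTGCC). Supplementary pairing was AGCT upstream of an 8mer or 7mer-m8 match, with 1 to 15 target bases between the partners of positions 8 and 13. For each library the median over site genes of log2 CPM, centred per gene, minus that over comparison genes gave its shift. Groups were compared by two-sided exact permutation of libraries, with intervals from inverting that test. Words of 7 bases carried by at least 20 genes were ranked by the rank-sum z of fold changes. Searches used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

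Genes are named by a rule. For each comparison it took the 8 largest falls and 8 largest rises among genes past the threshold with a mean of at least 5 CPM over its libraries, a symbol that is not a clone or locus name and no overlap between the groups. It added the 6 reported targets with the smallest adjusted p for miR-34a-WT against control, up to 3 members of each other list by the smallest adjusted p in any comparison, MIR34AHG and SIRT1, and the 6 genes with a supplementary-pairing site, at least 5 CPM and the smallest p between the miRNAs, 103 genes in all, of which 1 is not reported here. Genes named outside it are said to be named after their values were seen.

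The tests were tried on simulated data, the gene test on counts of 18321 genes with 200 changed. For miR-34a-WT against control the fit recovered 56%, 82%, 90% and 100% of genes changed by 1.25, 1.5, 2 and 4 times, for miR-34a-RS against control 62%, 76%, 90% and 100%, and for miR-34a-RS against miR-34a-WT 60%, 76%, 92% and 100%, and it called 7, 10 and 8 unchanged genes. With 60 genes changed, camera recovered both shifted lists in each comparison and called 1 unshifted list, between the miRNAs. The simulated genes varied independently, so this does not test camera where the members of a list vary together. For the real lists the estimated correlation reached 0.714, in mitochondrially encoded genes. Over 13608 genes a seed-site shift of -0.20 came back as -0.20, and over 2413 site genes a supplementary shift of 0.050 as 0.045. A shared variance of 0.090 put into all 18321 genes came back as a covariance of 0.091.

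Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, no or a stricter filter on low counts, only the compared groups in the fit, the replicate block, a minimum effect, leaving out each library in turn, other site definitions and gene sets, and, added after the data were seen, APPRIS principal transcripts and the removal of trends on 3′ UTR GC content and length. DESeq2 gave 10 adjusted p as NA, which were left so.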

Results

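Gene expression was measured by bulk RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, 24 h after transfection with 1 of 3 RNA duplexes. The control group of 5 libraries received AllStars, a commercial siRNA sold as a negative control. The miR-34a-WT group of 5 libraries received a duplex of miR-34a, a microRNA whose gene is activated by p53. The miR-34a-RS group of 4 libraries, replicates 1, 2, 3 and 5, received the same duplex with guide residues 13 and 14, counted from the 5′ end, replaced by rSpacer, an abasic residue that keeps the backbone and has no base to pair. The design asked what pairing beyond the seed, here guide positions 2 to 8, adds to the effect of a microRNA on its targets. Total counts per library ranged from 22.24 to 36.26 M, and 18321 genes had enough counts to be tested. The first principal component held 69.2% of the variance and placed all 5 control libraries on one side and all 9 microRNA libraries on the other. The share of counts from mitochondrially encoded genes was 3.002% ± 0.145 (SD, n = 5) in control, 3.05% ± 0.293 (SD, n = 5) with miR-34a-WT and 2.71% ± 0.374 (SD, n = 4) with miR-34a-RS, and it was lowest, at 2.19%, in miR-34a-RS replicate 2. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

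The first comparison, miR-34a-WT against control, asked which transcripts changed with the unmodified microRNA. NECTIN1, which encodes a cell adhesion protein, fell from 36.4 ± 2.6 to 6.68 ± 0.59 CPM (mean ± SD, n = 5 each), a log2 fold change of -2.44 (SE 0.07; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, adjusted p = 2.07e-18). RTL8B fell by 2.33 (SE 0.06), TPD52 by 2.05 (SE 0.08) and PPP1R11, which encodes an inhibitory subunit of protein phosphatase 1, by 1.92 (SE 0.05) on the log2 scale, each with an 8mer seed match in its 3′ UTR. The kinases of the G1 phase, CDK4 and CDK6, fell by 1.38 (SE 0.05) and 1.61 (SE 0.06) on the log2 scale, and the growth factor receptor gene MET fell by 1.36 (SE 0.06). Among the largest rises, LRGUK rose from 1.73 ± 0.27 to 9.19 ± 0.95 CPM (mean ± SD, n = 5 each; log2 fold change 2.41, SE 0.10), and OSCP1 and CCDC113 rose by 2.02 (SE 0.06) and 2.02 (SE 0.05) on the log2 scale, and BBOF1 from 4.488 ± 0.508 to 18.09 ± 1.07 CPM (mean ± SD, n = 5 each).

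Of the 18321 tested genes, 7373 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3469 higher and 3904 lower. The balance depended on the scaling, with 3750 higher and 3685 lower under DESeq2 size factors. With each library's trend on 3′ UTR GC content and length removed, an alternative added after the data were seen, 4375 were higher and 3302 lower among 13608 genes. With an added minimum of 0.5 in absolute log2 fold change, 623 were higher and 1409 lower. MPV17L2, SLC35G2, AP3B2 and SMPD1 completed the 8 largest falls, with log2 fold changes of -1.80 (SE 0.07), -1.75 (SE 0.08), -1.74 (SE 0.10) and -1.71 (SE 0.07). EFCAB6, LRRC46, DNAI3 and NEK10 completed the 8 largest rises, from 1.90 (SE 0.10) for EFCAB6 to 1.59 (SE 0.08) for NEK10. LRRC46 rose by 1.81 (SE 0.11) although its 3′ UTR carries an 8mer match. The library kit does not mark strand, so the values of MPV17L2, SLC35G2, BBOF1, LRRC46, DNAI3 and CDK4, and below of ANLN, XPO5, ATG4B, TAGLN and LOX, which overlap other genes on the opposite strand, are uncertain. The host transcript of the endogenous microRNA, MIR34AHG, fell by 0.45 on the log2 scale (SE 0.08), from 16.04 ± 0.835 to 11.73 ± 1.29 CPM (mean ± SD, n = 5 each).

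Of 50 measured genes on a list of reported miR-34a targets, 40 fell, 1 rose and 9 did not pass, against 41 and 2 adjusted over the list alone. HDAC1, a histone deacetylase gene, fell from 471 ± 10.8 to 247 ± 7.7 CPM (mean ± SD, n = 5 each), and NOTCH2 and ATG9A fell by 1.30 (SE 0.05) and 1.12 (SE 0.05) on the log2 scale. SIRT1, which encodes a deacetylase of p53 and histones, fell by 0.95 (SE 0.05). The member that rose was CTNNB1, at 0.15 (SE 0.04), and it was named after its value was seen. The list was lower than the other genes in the camera test (adjusted p = 6.57e-21), and this call held with an estimated correlation (adjusted p = 4.08e-05 with an estimated correlation).

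Genes of the cell cycle moved in both directions. In the G1/S and DNA replication list, 12 of 26 genes fell and 3 rose, with the same counts adjusted over the list alone. TK1, the thymidine kinase gene of S phase, fell from 134 ± 13.8 to 46.4 ± 3.7 CPM (mean ± SD, n = 5 each), and the helicase genes MCM3 and MCM2 fell by 0.87 (SE 0.04) and 0.72 (SE 0.04) on the log2 scale. The camera call of this list (adjusted p = 0.0234) was lost in the other form of the test (adjusted p = 0.334 with an estimated correlation). In the G2/M and mitosis list, 17 of 24 genes rose and 1 fell, against 18 and 1 adjusted over the list alone. ANLN, which encodes the contractile ring protein anillin, rose by 0.54 (SE 0.04), CKS2 by 0.53 (SE 0.05) and TPX2, which encodes a spindle assembly factor, by 0.32 (SE 0.03). The member that fell was PLK1, by 0.17 on the log2 scale (SE 0.06), named after its value was seen. Camera gave adjusted p = 1.67e-06 for the list, and the call was lost with adjusted p = 0.102 with an estimated correlation.

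In the Notch signalling list, 10 of 18 genes fell and 1 rose, with the same counts adjusted over the list alone. The receptor genes NOTCH2 and NOTCH3 fell by 1.30 (SE 0.05) and 0.95 (SE 0.06) on the log2 scale and the coactivator gene MAML1 by 0.46 (SE 0.04). The gene that rose, named after its value was seen, was RBPJ, which encodes the DNA-binding protein of the pathway, at 0.43 (SE 0.05). Camera gave adjusted p = 0.00235, lost with adjusted p = 0.206 with an estimated correlation. In the synaptic vesicle and exocytosis list, 11 of 18 genes fell and 3 rose, with the same counts adjusted over the list alone. SYT1, SYP and VAMP2, which encode proteins of vesicle membranes, fell by 1.66 (SE 0.08), 1.43 (SE 0.07) and 0.84 (SE 0.05) on the log2 scale. Camera gave adjusted p = 0.00235 for this list, and the call held with adjusted p = 0.0303 with an estimated correlation. NOTCH2, SYT1 and VAMP2 are also on the list of reported miR-34a targets, so the results of the Notch and synaptic vesicle lists are not independent of that list.

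The other 15 lists gave no camera call, with adjusted p from 0.145 to 0.779. Of p53 target genes 11 of 25 fell and 5 rose, and BTG2 fell by 1.47 (SE 0.08) on the log2 scale. Of Wnt signalling genes 8 of 28 fell and 4 rose, and LGR4, LEF1 and ZNRF3 fell by 0.96, 0.93 and 0.80 (SE 0.05, 0.06 and 0.05). Of genes of receptor tyrosine kinases and RAS-MAPK 10 of 32 fell and 11 rose, and KIT and FGFR1 fell by 1.38 (SE 0.07) and 0.83 (SE 0.05). In the unfolded protein response list 6 of 18 fell and 1 rose, with XBP1 at -1.35 (SE 0.07) and EDEM1 at 0.56 (SE 0.05). In the integrated stress response list 6 of 21 fell and 6 rose, with TRIB3 at -0.77 (SE 0.09) and SLC7A11 at 0.87 (SE 0.09). In the cholesterol biosynthesis list 8 of 21 fell and 5 rose, with DHCR7 at -0.83 (SE 0.05) and HMGCS1 at -0.51 (SE 0.05). In the lysosome and autophagy list 8 of 22 fell and 5 rose, with ATG9A, named above, at the largest fall and ATG4B at -0.38 (SE 0.05). In glycolysis 6 of 20 fell and 1 rose, with LDHA at -0.63 (SE 0.07), and in the BCL2 family 5 of 16 fell and 1 rose, with HRK at -0.57 (SE 0.07).

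In the epithelial-mesenchymal transition list 6 of 18 genes fell and 4 rose, with ZEB2 at 0.40 (SE 0.05) and ZEB1 at -0.27 (SE 0.05). In the small RNA machinery list 2 of 16 fell, XPO5 at -0.21 (SE 0.04) and TNRC6A, the latter named after its value was seen, and 4 rose, with TNRC6B at 0.43 (SE 0.06) and AGO2 at 0.30 (SE 0.06). In the interferon and double-stranded RNA response list 2 of 19 fell and 3 rose, with HERC5 at -0.30 (SE 0.06). Of 8 measured markers of fibroblasts 3 fell, TAGLN, COL3A1 and LOX, by 0.71 (SE 0.11), 0.64 (SE 0.13) and 0.61 (SE 0.09). None of the 3 measured blood cell markers changed, and none of the 13 mitochondrially encoded genes did. Adjusted over the list alone, 1 more gene rose in the small RNA machinery list, to 5, and in the integrated stress response list, to 7, and the counts of the 13 other lists were the same.

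The second comparison, miR-34a-RS against control, asked the same of the duplex without bases at positions 13 and 14. NECTIN1 again gave a large fall, to 7.66 ± 0.74 CPM (SD, n = 4) from 36.4 ± 2.6 CPM (SD, n = 5), a log2 fold change of -2.25 (SE 0.08; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.66e-17). PPP1R11 fell by 1.86 (SE 0.05), SNX12, which encodes a sorting nexin, by 1.83 (SE 0.05), both on the log2 scale, and MYB, a transcription factor gene, gave -1.76 (SE 0.10). CDK4 and CDK6 fell by 1.43 (SE 0.05) and 1.67 (SE 0.07), and MET by 1.38 (SE 0.06). CCDC113, OSCP1 and BBOF1 rose by 1.92 (SE 0.06), 1.81 (SE 0.06) and 1.70 (SE 0.08) on the log2 scale.

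In this comparison 6346 genes changed, 2968 higher and 3378 lower, and 605 and 1144 of them by at least 0.5 in absolute log2 fold change (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The balance turned with 3236 higher and 3183 lower under DESeq2 size factors, 3381 and 3102 under upper-quartile factors and 3134 and 2823 without a filter on low counts. With the trend on 3′ UTR GC content and length removed it was 3915 and 3091 among 13608 genes. SLC35G2, RTL8B, HAND1 and E2F5 completed the 8 largest falls, from -1.76 (SE 0.09) for SLC35G2 to -1.67 (SE 0.06) for E2F5. LRRC46, DNAI3, PIH1D2, MAPK15 and CLBA1 completed the 8 largest rises, from 1.68 (SE 0.11) for LRRC46 to 1.31 (SE 0.06) for CLBA1. E2F5, PIH1D2 and CLBA1 also overlap expressed genes on the opposite strand, so their values are uncertain. SIRT1 fell by 0.68 (SE 0.05) and MIR34AHG by 0.27 (SE 0.08) on the log2 scale, and the call of MIR34AHG was lost without miR-34a-RS replicate 1.

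Of 50 reported miR-34a targets 39 fell and 1 rose, again CTNNB1, against 40 and 2 adjusted over the list alone (camera adjusted p = 2.21e-25, and adjusted p = 1.39e-05 with an estimated correlation). In the G1/S and DNA replication list 11 of 26 fell and 3 rose, with TK1 at -1.48 (SE 0.08) and MCM3 at -0.98 (SE 0.04), and the counts were the same adjusted over the list alone. Camera gave adjusted p = 0.00860, lost with adjusted p = 0.240 with an estimated correlation. In the G2/M and mitosis list 15 of 24 rose and 1 fell, with CKS2 at 0.46 (SE 0.06) and ANLN at 0.39 (SE 0.05), and the counts were the same adjusted over the list alone. Camera gave adjusted p = 1.93e-04, lost with adjusted p = 0.240 with an estimated correlation. In the Notch signalling list 9 of 18 fell and 1 rose, with NOTCH2 at -1.27 (SE 0.06) and NOTCH3 at -0.56 (SE 0.06), against 10 and 1 adjusted over the list alone. The list had camera adjusted p = 0.00860, lost with adjusted p = 0.240 with an estimated correlation. In the synaptic vesicle list 10 of 18 fell and 2 rose, with SYT1 at -1.58 (SE 0.09) and SYP at -1.14 (SE 0.07), against 11 and 2 adjusted over the list alone. The list had camera adjusted p = 0.00860, lost with adjusted p = 0.0684 with an estimated correlation. The other 15 lists had camera adjusted p from 0.0648 to 0.998. Among them 2 mitochondrially encoded genes fell, MT-ND3 at -0.19 (SE 0.06) and MT-ND6 at -0.17 (SE 0.06), beside the lower mitochondrial share of these libraries, calls lost in 2 and 12 of the 24 other settings, and 1 of the 13 fell adjusted over the list alone.

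Seed matches set the falls apart in both comparisons. A gene with an 8mer (CACTGCCA) or 7mer-m8 (CACTGCC) match in its 3′ UTR was a site gene, and a gene without any 6mer of the seed was a no-site gene, giving 2413 and 8828 tested genes. Of genes with an 8mer 52.2% fell with miR-34a-WT and 50.1% with miR-34a-RS, against 1524 and 1239 of 8828 no-site genes. Per library, the median log2 level of site genes relative to no-site genes was 0.12 ± 0.022 (SD, n = 5) in control, -0.072 ± 0.018 (SD, n = 5) with miR-34a-WT and -0.060 ± 0.013 (SD, n = 4) with miR-34a-RS. The shift from control was -0.19 for miR-34a-WT (95% interval -0.22 to -0.16) and -0.18 for miR-34a-RS (95% interval -0.21 to -0.14), each with p = 0.00794 in a two-sided exact permutation test of libraries, the smallest value these libraries allow. For miR-34a-WT and miR-34a-RS in turn, the shift was -0.25 and -0.24 for genes with an 8mer, -0.16 and -0.14 for 7mer-m8, -0.093 and -0.12 for 7mer-A1 and -0.072 and -0.076 for 6mer genes. Of all words of 7 bases, the match CACTGCC had the lowest rank-sum z across genes in both comparisons, at -23.5 and -24.0, as a description across genes, which are not independent replicates. The match of the passenger strand, GCTGATT, ranked 7841 and 5133 from the lowest, and 1265 and 2967 with fold changes as residuals on 3′ UTR length and GC content. Between the miRNAs, CACTGCC ranked 14970 from the lowest.

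**Figure D1:**
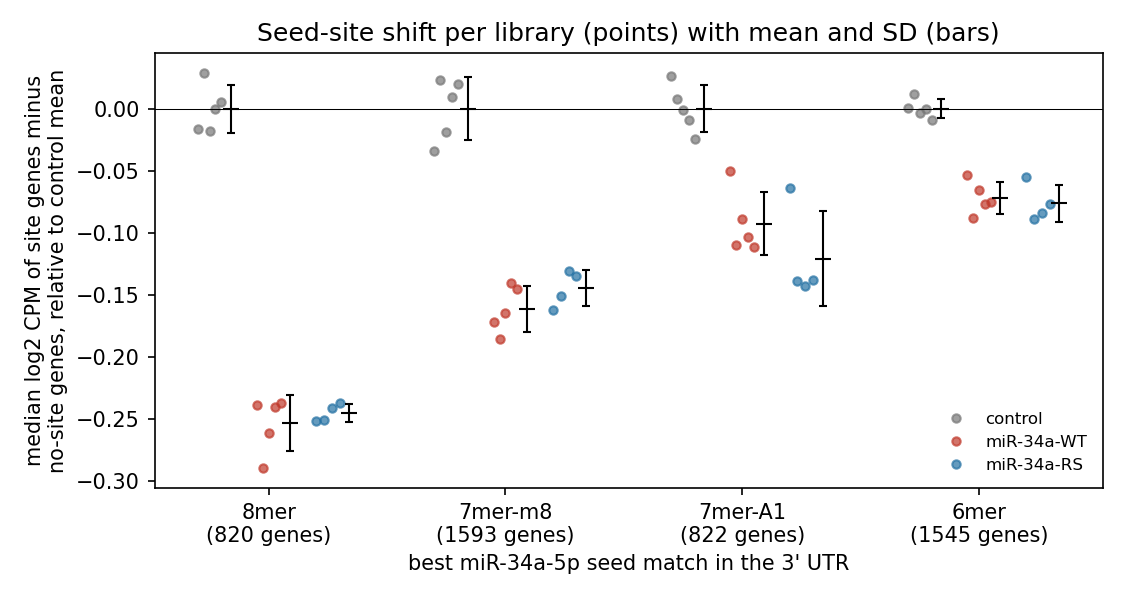
Median log2 CPM of genes with each class of miR-34a-5p seed match minus that of no-site genes, relative to the control mean, for each library (points), with the mean and SD of each group (bars). Libraries with either miRNA lie below the control libraries in each class, and the shift is larger for 8mer genes (-0.25 with miR-34a-WT and -0.24 with miR-34a-RS) than for 6mer genes (-0.072 and -0.076).

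The third comparison, miR-34a-RS against miR-34a-WT, asked what changed when positions 13 and 14 could not pair. MPP2, which encodes a membrane scaffold protein of the MAGUK family, was 80.35 ± 4.55 CPM (SD, n = 5) in control, 25.8 ± 0.94 CPM (SD, n = 5) with miR-34a-WT and 46.0 ± 1.4 CPM (SD, n = 4) with miR-34a-RS, and was higher with miR-34a-RS than with miR-34a-WT by 0.84 on the log2 scale (SE 0.05; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.59e-10). RBM38, an RNA-binding protein gene activated by p53, was 28.5 ± 1.5 CPM (SD, n = 5) with miR-34a-WT and 49.05 ± 3.89 CPM (SD, n = 4) with miR-34a-RS, higher by 0.78 (SE 0.06). RCAN1, which encodes a regulator of calcineurin, was higher by 0.70 (SE 0.06), and SH3GL1 by 0.66 (SE 0.06). PIP4P2 was higher by 0.66 (SE 0.10), PCOLCE2 by 0.64 (SE 0.07), GINS1, which encodes a subunit of the replication complex GINS, by 0.61 (SE 0.06), and RTL8B by 0.61 (SE 0.07). The largest falls were smaller, with PRRG4 at -0.46 (SE 0.08), GALNT7 at -0.43 (SE 0.06), LRGUK at -0.41 (SE 0.09) and GPR137B at -0.41 (SE 0.07).

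In this comparison 286 genes changed, 188 higher and 98 lower with miR-34a-RS, and 36 and 2 of them by at least 0.5 in absolute log2 fold change. With the replicate number as a block, since same-numbered libraries of these 2 groups deviated together, 1254 genes changed, 625 higher and 629 lower, and 285 of the 286 were among them. With each library's trend on 3′ UTR GC content and length removed, an alternative added after the data were seen, 734 of 13608 genes changed, 332 higher and 402 lower. KLHL15, ZMYND11, CHIC1 and RAPGEF6 completed the 8 largest falls, from -0.39 (SE 0.06) for KLHL15 to -0.34 (SE 0.07) for RAPGEF6, and the calls of LRGUK and RAPGEF6 were lost in 4 and 3 of the 24 other settings. GPR137B overlaps an expressed gene on the opposite strand, so its value is uncertain. The count of changed genes was 730 without miR-34a-RS replicate 1, between 142 and 176 without miR-34a-RS replicate 2, 3 or 5 or miR-34a-WT replicate 1 or 3, and within 1.5 times of 286 without any other library.

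Among changed genes with a 3′ UTR, 70 of 185 that were higher with miR-34a-RS were site genes (37.8%), against 19 of 95 that were lower and 17.4% of genes that did not pass. These shares are from the fit without the replicate block and with trends on 3′ UTR GC content kept, and were not counted in other fits. With fold changes as residuals on 3′ UTR length and GC content, the z of CACTGCC between the miRNAs moved from 4.35 to 0.73. The shift of site genes as a whole was 0.012 (95% interval -0.014 to 0.040; two-sided exact permutation p = 0.294), so that a difference beyond 0.040 lies outside the interval. Most reported targets did not pass in this comparison. Of the 50, 2 rose and 3 fell, against 2 and 5 adjusted over the list alone. SIRT1 was higher by 0.27 (SE 0.05; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00888). The other 4, named after their values were seen, were IL6R, higher by 0.81 (SE 0.12), and CCND1, CDC25A and E2F3, at -0.31 (SE 0.08), -0.19 (SE 0.04) and -0.17 (SE 0.04). CDK4, CDK6 and MET differed by -0.04 (95% interval -0.14 to 0.06), -0.06 (95% interval -0.21 to 0.08) and -0.03 (95% interval -0.15 to 0.10), without passing the test.

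Genes of cholesterol biosynthesis were higher with miR-34a-RS than with miR-34a-WT. Of 21 measured, 5 rose and none fell, against 11 and 0 adjusted over the list alone, and the call held in both forms of camera (adjusted p = 9.92e-13, and adjusted p = 9.65e-05 with an estimated correlation). Against control camera called the list with neither miRNA. Its median log2 fold change was -0.009 with miR-34a-WT (5 rose, 8 fell, camera adjusted p = 0.319) and 0.086 with miR-34a-RS (8 rose, 4 fell, camera adjusted p = 0.264). SREBF2, the transcription factor gene that activates this pathway, was 106.5 ± 3.02 CPM (SD, n = 5) with miR-34a-WT and 146 ± 7.2 CPM (SD, n = 4) with miR-34a-RS, higher by 0.46 (SE 0.05). HMGCS1, which encodes an enzyme early in the pathway, was higher by 0.38 (SE 0.05). The other 3, named after their values were seen, were MVD at 0.44 (SE 0.08), IDI1 at 0.21 (SE 0.05) and FDFT1 at 0.16 (SE 0.04). HK1, a hexokinase gene and the single glycolysis gene of 20 that passed, was higher by 0.44 (SE 0.04), also adjusted over the list alone.

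Camera called 5 further lists in this comparison, and all 5 calls were lost with an estimated correlation. The counts of members here and in the lists above are from the fit without the replicate block. More genes changed with the block, so a member that did not pass may pass with it. None of 25 p53 target genes passed, over all genes or adjusted over the list alone (adjusted p = 0.00389, higher, and adjusted p = 0.345 with an estimated correlation). Of 24 G2/M genes 1 fell, HMMR at -0.23 (SE 0.06), named after its value was seen, against 5 adjusted over the list alone (adjusted p = 9.91e-04, lower, and adjusted p = 0.292 with an estimated correlation). None of 16 small RNA machinery genes passed, against 5 that fell adjusted over the list alone (adjusted p = 0.00437, lower, and adjusted p = 0.292 with an estimated correlation). Of 16 BCL2 family genes 1 rose, MCL1 at 0.16 (SE 0.04), named after its value was seen, against 2 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.0491, higher, and adjusted p = 0.345 with an estimated correlation). None of 13 mitochondrially encoded genes passed, over all genes or adjusted over the list alone, beside the low mitochondrial share of miR-34a-RS replicate 2 (adjusted p = 2.09e-07, lower, and adjusted p = 0.292 with an estimated correlation). The other 14 lists had camera adjusted p from 0.0711 to 0.985, and NOTCH3 at 0.39 (SE 0.06) and XBP1 at 0.31 (SE 0.08) were members of them that rose. The call of XBP1 was lost in 12 of the 24 other settings.

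**Figure D2:**
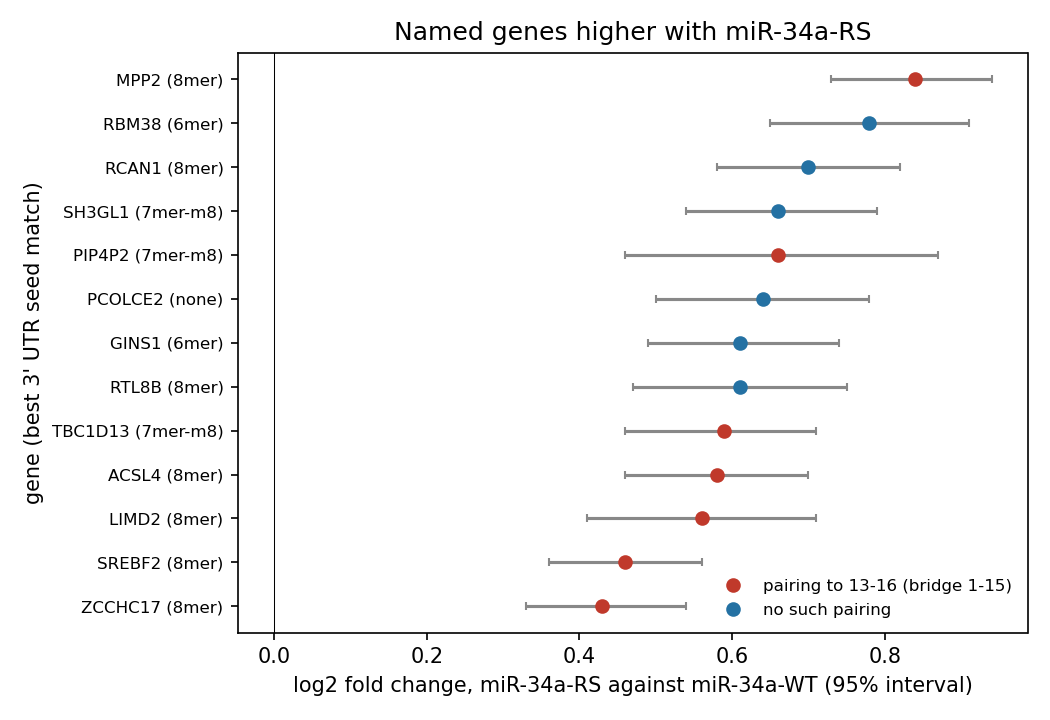
Log2 fold change of miR-34a-RS (n = 4) against miR-34a-WT (n = 5) for the 8 genes with the largest rises and the 6 genes with pairing to guide positions 13 to 16 and the smallest p, 1 of which is in both sets (points, with 95% intervals from edgeR's standard errors). Red points are genes with 4 pairs to positions 13 to 16 upstream of a seed match, and MPP2 lies highest at 0.84.

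Sites able to pair with the abasic positions were compared within the site genes. In 223 of the 2413, a seed match was preceded by AGCT, the complement of guide positions 13 to 16, across a bridge of 1 to 15 target bases. These genes were lower than the other 2190 site genes by -0.047 with miR-34a-WT against control (exact permutation p = 0.00794) and by -0.025 with miR-34a-RS against control (exact permutation p = 0.0159), on the log2 scale. The reordered control word TGCA gave similar values against control, -0.040 (exact permutation p = 0.00794) and -0.027 (exact permutation p = 0.0159), and CATG gave 0.078 and 0.083, so the falls against control do not single out pairing with these positions. The difference between the miRNAs for AGCT was 0.022 (95% interval 0.0030 to 0.042; two-sided exact permutation p = 0.0397). Between the miRNAs, of 3 reordered control words, TGCA gave 0.014 (exact permutation p = 0.0397), GATC -0.020 (exact permutation p = 0.0317) and CATG 0.0050 (exact permutation p = 0.667). The call was lost in 8 of the 9 fits without 1 library, with 0.014 without miR-34a-RS replicate 5 and 0.010 and 0.0070 without miR-34a-WT replicates 2 and 3, and with 0.011 on APPRIS principal transcripts and 0.016 as residuals on 3′ UTR GC content and length (exact permutation p = 0.0794), both alternatives chosen after the data were seen. With 5 pairs, to positions 13 to 17, an alternative set beforehand, the difference was 0.057 (exact permutation p = 0.0238). Paired by replicate number the main difference was 0.022, where 4 pairs allow no exact sign-flip p under 0.125.

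With the bridge restricted to 2 to 6 bases, 86 genes were higher with miR-34a-RS than with miR-34a-WT by 0.070 relative to other site genes (95% interval 0.045 to 0.094; exact permutation p = 0.00794). Their shift against control was -0.16 with miR-34a-WT and -0.089 with miR-34a-RS. Paired by replicate number the difference between the miRNAs was 0.076, above 0 in 4 of 4 pairs, where 4 pairs allow no exact sign-flip p under 0.125. The restricted bridge was among the alternatives set before the data were examined, as were the tests, gene lists and rule for named genes. In a scan of 11 windows of 4 guide positions at matching offsets, chosen after the data were seen, the difference was 0.070 at positions 13 to 16 (adjusted p = 0.0437, exact permutation with Benjamini-Hochberg adjustment over windows) and 0.062 at positions 14 to 17 (adjusted p = 0.0437), and no other window had an adjusted p under 0.142. Of the other windows that include an abasic position, 12 to 15 gave 0.050, but 11 to 14 and 10 to 13 went the other way, at -0.017 and -0.059. The window at 15 to 18, without an abasic position, gave 0.054.

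**Figure D3:**
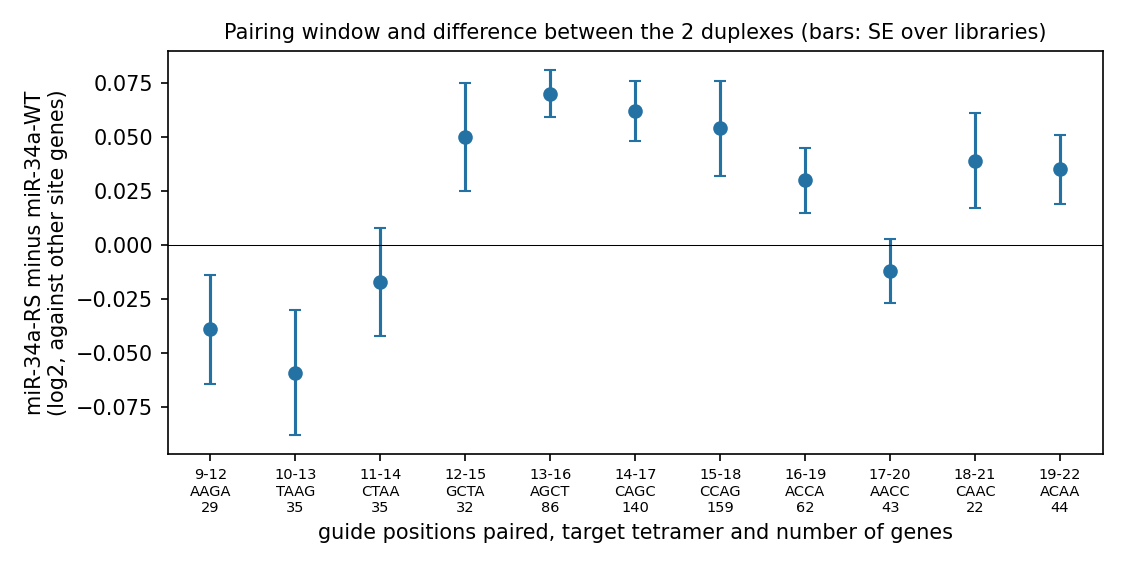
Difference between miR-34a-RS (n = 4) and miR-34a-WT (n = 5) in the median log2 level of site genes with 4 pairs to each window of guide positions, relative to the other site genes (points; bars are the SE over libraries). The target tetramer and number of genes stand under each window. The windows at 13 to 16 and 14 to 17 lie at 0.070 and 0.062, and the window at 15 to 18, without an abasic position, at 0.054. The windows at 11 to 14 and 10 to 13, which include abasic positions, lie at -0.017 and -0.059.

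Several of the genes that were higher with miR-34a-RS had such a site in the annotated 3′ UTR (GRCh38, GENCODE 29). MPP2 has a 7mer-m8 match on chromosome 17 from 43877127 to 43877133, minus strand, with AGCT at a bridge of 3 bases in the sequence CCTTCCCTCATCCACAGCTTCTCACTGCC. Its 3′ UTR holds 2 other seed matches without this pairing. The match of ACSL4, which encodes an acyl-CoA synthetase, lies on chromosome X from 109642109 to 109642116, minus strand, at a bridge of 4, and the gene was higher by 0.58 (SE 0.06). The match of TBC1D13 lies on chromosome 9 from 128809943 to 128809949, plus strand, at a bridge of 5, and that gene was higher by 0.59 (SE 0.06). PIP4P2 has its match on chromosome 8 from 90994560 to 90994566, minus strand, at a bridge of 4. For ZCCHC17, higher by 0.43 (SE 0.05), the match is on chromosome 1 from 31364495 to 31364502, plus strand, at a bridge of 2. LIMD2, higher by 0.56 (SE 0.07), has its match on chromosome 17 from 63698184 to 63698191, minus strand, at a bridge of 4, but overlaps other expressed genes, so its value is uncertain. The match of SREBF2, on chromosome 22 from 41905639 to 41905646, plus strand, has a longer bridge of 9. Most of these genes were named for a small p between the miRNAs, so their rises are no test of the pairing. PPP1R11 did not follow, since a match on chromosome 6 from 30069669 to 30069676, plus strand, with a bridge of 2 stood beside a difference of 0.06 (95% interval -0.06 to 0.17). Nor did TNRC6B, which has a match on chromosome 22 from 40329680 to 40329686, plus strand, at a bridge of 9. It did not pass between the miRNAs and had risen with miR-34a-WT against control. Of the 8 genes with the largest rises, only MPP2 and PIP4P2 had this pairing in the 3′ UTR. RCAN1, RTL8B and SH3GL1 had an 8mer or 7mer-m8 match without it, RBM38 and GINS1 a 6mer alone and PCOLCE2 no seed match there.

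The responses to both miRNAs were close across genes. Of the genes that rose with miR-34a-RS, 2514 also rose with miR-34a-WT (84.7%), where independent lists of these sizes would share 562, and 2886 fell with both (85.4% of those that fell with miR-34a-RS), where independent lists would share 719.8. CCDC113 and OSCP1 were among the genes higher in both and NECTIN1 and PPP1R11 among those lower in both, and 3 genes changed in opposite directions. The covariance of the log2 fold changes was 0.12 (Pearson's r = 0.889 across 18321 genes, which are not independent replicates). All 14 libraries were also simulated 20 times as unchanged groups, with 5 simulated controls shared by both miRNAs. These gave a mean covariance of 0.011 (r = 0.480), so the observed value exceeded it by 0.11. With the controls split so that each miRNA had its own, the covariance was 0.10 in both splits (r = 0.715 and 0.690). The simulated libraries were drawn independently. Deviations shared by same-numbered miRNA libraries, and any effect of the control siRNA, are therefore not in the simulated value, and splitting the controls removes neither. The excess is thus not a measure of a shared miR-34a response alone. Within site genes, the slope of the miR-34a-RS on the miR-34a-WT fold changes was 0.878.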

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

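The tests of other orders of the tetramer, the coding residuals and the predictions for other splits were chosen only after the results were seen, and the reading of the tetramer and coding-region tests, predicted beforehand, was made stricter after.

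In 17 of 324 groups of values 1 library stood apart from the others of its group, where chance gives about 1 in 20, or 16.2. Control replicate 1 had the lowest level of 4 genes, at 31.9 CPM for NECTIN1 (others 36.6 to 38.3), 116 CPM for SH3GL1 (others 141 to 143), 453 CPM for HDAC1 (others 472 to 479) and 141 CPM for DHCR7 (others 157 to 163), and the highest of HMGCS1, at 102 CPM (others 94.0 to 95.6). Control replicate 5 was lowest for E2F5 at 39.4 CPM (others 42.2 to 43.2) and for SYT1 at 10.2 CPM (others 11.8 to 12.4). The share of mitochondrially encoded counts was lowest among controls in replicate 2, at 2.75% (others 3.02% to 3.10%). Among miR-34a-WT libraries, replicate 1 was highest for SMPD1 at 5.69 CPM (others 4.54 to 4.76), and replicate 2 was highest for MCM3 at 284 CPM (others 257 to 264), CKS2 at 142 CPM (others 119 to 123) and HERC5 at 28.0 CPM (others 23.8 to 24.3). Replicate 3 was highest for DHCR7 at 92.8 CPM (others 87.0 to 87.8), replicate 4 for MT-ND6 at 747 CPM (others 625 to 660), and replicate 5 was lowest for COL3A1 at 1.02 CPM (others 1.55 to 1.77). Among miR-34a-RS libraries, replicate 1 was lowest for CTSB at 51.6 CPM (others 56.5 to 57.0) and replicate 2 for MT-ND6 at 518 CPM (others 617 to 626).

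Site genes with pairing to positions 13 to 16 across a short bridge were higher with miR-34a-RS than with miR-34a-WT by 0.070, a pattern singled out because, of the definitions tried, it exceeded the 0.022 of the main one by most. With each library's trend on 3′ UTR GC content and length removed the difference was 0.058 (exact permutation p = 0.00794), which argues against those trends as the whole cause. The same tetramer downstream of the match gave 0.014 (95% interval -0.016 to 0.047), too wide to exclude an effect of the tetramer itself, and although AGCT ranked 1 of 18 orders of its bases, TAGC at 0.055 and ATGC at 0.051 came close and lie inside the interval of AGCT (0.045 to 0.094). Among all 225 tetramers carried by at least 20 site genes at this bridge, AGCT ranked 6, at 0.067 by gene fold changes. CGCT, CAGC, CGGC, GCTG and TAGC ranked above it, at 0.098 to 0.069, and of these CAGC is the complement of guide positions 14 to 17. Coding-region matches in genes without a 3′ UTR 6mer gave 0.055 (exact permutation p = 0.00794; 0.042 with coding GC and length removed), as loss of pairing at the abasic positions may produce, but 0.024 (p = 0.127, exact permutation) over bridges of 1 to 15 bases. In the same genes the reordered word TGCA gave 0.044. GCTA gave 0.10, but it is the complement of guide positions 12 to 15, which include both abasic positions, so its value does not weigh against loss of pairing. In the 3′ UTR scan, however, positions 11 to 14, which also include both, gave -0.017. Loss of pairing thus remains a hypothesis from the same libraries that prompted it.

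Other splits of the libraries show whether chance can be excluded. In fits of the 2 groups alone, with 100 splits drawn per comparison, the real split was the single 1 of 100 to give as many genes in each. It gave 7538 genes for miR-34a-WT against control (highest other 0) and 6087 for miR-34a-RS against control (highest other 1731, in a split that set 4 of the 5 controls against the rest). A chance division of these libraries is thus an unlikely source of these counts. The other splits mix treated and control libraries, which widens the spread within groups, and they do not weigh handling shared by the libraries of a group. Between the miRNAs it gave 218 (highest other 17), but most of these splits ignore the pairs of libraries. For lists, 24 of 100 splits gave as many as the real 5 for miR-34a-WT (highest other 11), 20 of 100 as many as the 5 for miR-34a-RS (highest other 8), and 16 of 100 as many as the 6 between the miRNAs (highest other 8), so chance cannot be excluded for the number of lists. Of 11 drawn splits that part all 4 pairs between the miRNAs, the most genes in any was 0 and the most lists 6. With libraries taken as pairs only such splits are like the real one, and 11 are too few to exclude chance for the 218 genes.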

How the results depend on the processing

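The tests with 3′ UTR GC and length trends removed (except in the scan of words), the block within only 2 groups and APPRIS transcripts were chosen after the data were seen. Values without a stated cause are ones where the cause was not tested.

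No called direction of a named gene or list reversed under an alternative, and other genes were not counted for this. Between miR-34a-RS and miR-34a-WT the 286 changed genes became 1254 with the replicate block, 2338 with the block in only the 2 groups, 446 with DESeq2 (255 higher, 191 lower), 734 with the GC and length trend removed, and 1368 with both that removal and the block. A minimum effect, which by construction lowers counts, left 38 there, 2032 for miR-34a-WT and 1749 for miR-34a-RS against control. Against control the block gave 8817 and 7715 genes and 7 lists each, but same-numbered libraries correlated at -0.18 to 0.58 and -0.03 to 0.51 (mean 0.31 and 0.27, against -0.07 for others) and not each best with its own number, so they were not taken as pairs, though shared handling of some is not excluded. With an estimated correlation 2, 1 and 1 lists were called in the 3 comparisons, and with fry 14, 12 and 1. Between the miRNAs the block changed no list call of camera with the preset correlation, while fry with the block called 6 more lists (adjusted p = 0.0120 for p53 target genes, 0.0206 for synaptic vesicle and exocytosis, 0.0234 each for G2/M and mitosis, the BCL2 family and mitochondrially encoded genes and 0.0263 for fibroblast markers).

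Seed-site shifts with the block were -0.19 and -0.18 (exact sign-flip p = 0.0625 and 0.125), and -0.13 and -0.13 with GC and length residuals and the block, the smallest p that 5 and 4 pairs allow. The supplementary shift of 0.022 was 0.011 on APPRIS transcripts, 0.022 with the block, 0.016 as residuals (exact permutation p = 0.0794, the call lost) and 0.015 as residuals with the block, and 0.062 for the short bridge as residuals with the block. It kept its call at 0.057 with 5 pairs to positions 13 to 17 (exact permutation p = 0.0238), 0.026 with 7mer-A1 sites included, 0.027 as a mean and 0.023 over genes of at least 10 CPM. The covariance moved to 0.10 with a stricter filter, 0.10 and 0.10 with split controls and 0.15 in site genes. The seed match moved to rank 2 for miR-34a-RS against control as residuals, and between the miRNAs to 10977 as residuals and 15042 on APPRIS transcripts.

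Without 1 library in turn, changed genes ranged from 6742 to 7699, 5648 to 6454 and 142 to 730, and lists from 4 to 5, 5 to 7 and 3 to 7, the lowest without miR-34a-RS replicate 2. Changed genes between the miRNAs were 730 without miR-34a-RS replicate 1, and 143, 142 and 176 without its replicates 2, 3 and 5, and 175 and 151 without miR-34a-WT replicates 1 and 3. Seed-site shifts ranged from -0.20 to -0.18, -0.18 to -0.17 and 0.0070 to 0.018, and the supplementary shift from 0.0070 to 0.023. The latter lost its call in 8 of 9 leave-outs, at 0.018, 0.017 and 0.014 without miR-34a-RS replicates 1, 2 and 5 and 0.018, 0.010, 0.0070, 0.015 and 0.018 without miR-34a-WT replicates 1 to 5.

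Of 7386 alternative values of the named genes 7153 kept call and direction, 128 lost and 105 gained a call. For miR-34a-WT none of 95 calls was lost in any setting, for miR-34a-RS 9 of 93, and between the miRNAs 8 of 33. The planned choice of the longest 3′ UTR equals the main choice, because GENCODE 29 has no canonical tags, and was not run.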

Other observations

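The tests of the cilia lists, GC slope and TTACAAA were chosen after those patterns were seen, with their outcomes predicted beforehand, and the test over orders of the word and the stricter readings of the GC slope tests were chosen only after the result was seen.

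Genes of motile cilia rose with both miRNAs. In a list of 48 drawn up because several of the largest rises were such genes, and without those genes, 31 of 40 tested rose and none fell with miR-34a-WT (median log2 fold change 0.76), and 28 rose and none fell with miR-34a-RS (median 0.66). DNAAF1, which encodes a dynein assembly factor, rose from 1.68 ± 0.29 to 8.10 ± 0.89 CPM (mean ± SD, n = 5 each), and DNAH7, a dynein heavy chain gene, from 0.925 ± 0.168 to 5.58 ± 0.72 CPM. FOXJ1, the transcription factor gene of motile cilia, was low throughout, at 0.0939 ± 0.071 CPM in control and 0.935 ± 0.178 CPM with miR-34a-WT. Camera held with an estimated correlation (adjusted p = 2.07e-06 and 2.09e-06). In a list of 24 intraflagellar transport and BBSome genes 20 rose and none fell with each (median 0.40 and 0.35; adjusted p = 4.37e-04 and 3.61e-04 with an estimated correlation), with IFT88 at 1.19 (SE 0.05) with miR-34a-WT. Between the miRNAs none of the 40 motile cilia genes passed edgeR's test, with a median of -0.09 (camera adjusted p = 0.0122 with an estimated correlation). A general rise of the ciliary programme is a hypothesis that the median of 0.755 fits, and what drives it was not tested.

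Per-library slopes of level on 3′ UTR GC content differed most between miR-34a-WT and control, by -0.079 log2 per 10% GC (95% interval -0.145 to -0.019; exact permutation p = 0.0238; lower in 5 of 5 same-numbered libraries), and by -0.040 between miR-34a-RS and control (p = 0.286, exact permutation). The tests below weighed the difference between the miRNAs, which was 0.039 (95% interval -0.037 to 0.11; exact permutation p = 0.238). The slope was higher with miR-34a-RS in 4 of 4 pairs, so the planned reading of a p above 0.05 as differences between libraries that do not follow the groups was not kept, and the 2 cannot be told apart with 4 pairs. Over genes of at least 10 CPM the difference was 0.035, which speaks against noise of low counts but with too wide an interval to exclude it.

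Genes with TTACAAA in the 3′ UTR, the word with the highest z against control after GC and length removal (10.6 and 11.1, 2827 genes), were higher by 0.060 with miR-34a-WT and 0.063 with miR-34a-RS. A seed effect of the control siRNA, whose sequence was not used here, could leave its targets lower in control. Genes with the word followed by A exceeded those with another base by 0.019 and 0.022 (exact permutation p = 0.00794 each), but that difference ranked 19 and 16 among 105 orders of the same bases. TTACAAA itself ends in A, so these ranks do not weigh against a seed match to the overlapping word ATTACAA. That word ranked 2 by z in both comparisons with control after GC and length removal. Followed by A, it exceeded ATTACAA with another base by 0.047 and 0.042, ranks 1 and 2 of the 105 orders. It was picked out after these ranks were seen, so a seed effect and A-rich sequence both stay open. A general release of targets of endogenous miRNAs is argued against, since 0 of 5 abundant families had their match in the top 5% of words in both comparisons, but for single families it stays open, because the miR-17 match GCACTTT ranked 334 from the highest with miR-34a-WT and 1971 with miR-34a-RS, and between the miRNAs the miR-17 match was the lowest word of all (z = -5.6) and the miR-92 and miR-16 matches ranked 16378 and 16324 from the highest.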
